A study of Homo sapiens with 9 samples.

How the data were processed

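RNA from 9 cultures of the LX2 line was sequenced, 3 for each of a non-targeting siRNA (siNT), an siRNA against YAP (siYAP) and an siRNA against TAZ (siTAZ). Per the labels, cells grew in serum-containing medium, were transfected with 20 nM siRNA by lipofection and were kept for 7 days, and libraries were made with an mRNA kit from total RNA extracted with Trizol. The siRNA sequences, and whether each reagent was a pool, are not given. The design text names siNT in the place of siTAZ once; the sample labels name 3 siTAZ libraries, and grouping followed the labels.

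The deposited values are raw read counts per Ensembl gene, 1 library per file, with no normalization. The authors name Trim Galore, STAR 2.5.0c, SAMtools, Picard and HTSeq as the tools that made these counts, without settings. The build named with them is mm10, a mouse build, whereas every gene ID in the files is human, so the build, the annotation release and the strand setting behind the counts are not known. Totals per library lay between 16498508 and 18752805 counts in genes, and a floor of 3 counts corresponds to 0.157 to 0.177 CPM (counts scaled to a common library size, here with TMM); this floor covers counting error only. Of 36601 genes, 10252 had no count in any library. Names came from a gene name table for 36366 IDs and from GENCODE release 29 for 219, and 25540 IDs received a symbol. Coordinates and overlaps between genes are those of GENCODE 29 on GRCh38.

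Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with the groups given (minimum count 10, minimum total count 15), which left 15560 genes holding at least 99.862% of the counts of each library. Libraries were scaled by TMM, and CPM values use the scaled library sizes. A quasi-likelihood model with robust estimation was fitted over all 9 libraries (common biological coefficient of variation 0.0469, median prior degrees of freedom 55.3). The comparisons were siYAP with siNT, siTAZ with siNT, and siTAZ with siYAP, the last of which tests the difference between the knockdown effects. Each used edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes come from the same fit.

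Gene lists, 35 in number and holding 843 genes, of which 842 matched an ID, were tested with limma's camera at a preset inter-gene correlation of 0.01. Benjamini-Hochberg adjustment ran over the 34 lists with at least 5 tested members. Calls were repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance in a direction and does not compare them with other genes. Counts of members rest on the adjustment over all genes, and counts adjusted over the list alone are given where they differ. The genes named were the 6 largest rises and 6 largest falls per comparison among called genes with a symbol, an average log2 CPM of at least 3 and no overlap between the libraries of the groups; YAP1, WWTR1 and TEAD1 to TEAD4; a panel of 21 fibrosis, Hippo, cell cycle and cytokine genes, of which 20 are described; and for each called list up to 4 called members with the smallest p in its direction and up to 2 in the other. The comparisons, tests, lists, naming rule and alternatives, except those said to be added later, were chosen before the data were examined.

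The overlap of calls was set against independent lists of the same sizes and against 50 simulations of unchanged groups with shared controls. The fits were tested on simulated data of 15560 genes, with 50 genes changed at each of 1.2-, 1.5-, 2- and 4-fold. In the siYAP layout 18, 30, 40 and 49 of them were recovered, and in the siTAZ layout 16, 40, 46 and 46. False calls numbered 13 and 17, a larger share of all calls than the threshold of 0.05 allows on average. A list shifted as a whole was called and 0 unchanged lists were called, in simulations that drew each gene independently. They do not show how often unchanged lists of correlated genes would be called. Alternatives were RLE and upper-quartile scaling, no filter and a stricter one (CPM of at least 1 in 3 libraries), the replicate number as a block, a fit over the compared groups alone, DESeq2, limma-voom, each library left out in turn, an adjusted p under 0.01, and edgeR's test against a fold of 1.5. A further alternative, chosen after seeing the data, left out genes whose 3' UTR holds a 6-base word related to either siRNA group. These words were GGATAA for siYAP and ATGAAC for siTAZ, so genes that hold only other words stayed in.

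For words in 3' UTRs, the 10155 genes with an average log2 CPM of at least 3 and an annotated 3' UTR of at least 50 bases were used. Each of 15702 words of 7 bases found in at least 100 genes was given a t value for its relation to the log2 fold change (limited to 2 in size) in a linear model with UTR length and GC content, and 100 permutations of the genes gave the chance level. Words planted in simulated data with a log2 shift of -0.2 were found again in 8 of 10 cases for siYAP and 10 of 10 for siTAZ. These steps and the figures used Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9. No library was left out. Counts outside annotated genes entered no test.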

Results

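RNA was sequenced from LX2 cells, an immortalised line of human hepatic stellate cells, the liver cells that turn into collagen-producing myofibroblasts during fibrosis. The cells had received 20 nM of a non-targeting siRNA (siNT), an siRNA against YAP (siYAP) or an siRNA against TAZ (siTAZ) and were kept for 7 days. YAP (gene symbol YAP1) and TAZ (WWTR1) are related transcriptional coactivators of the Hippo pathway that act mainly through the TEAD family of DNA-binding proteins. Each of the 3 groups held 3 libraries, labelled as biological replicates without a statement of what separated them, so the p-values measure only the spread between these libraries. The libraries carried between 16498508 and 18752805 counts in genes, and with TMM scaling 1 count was worth between 0.0522 and 0.0591 CPM (counts scaled to a common library size). Of 36601 genes in the files, 15560 had enough counts to be tested. Log2 CPM correlated across genes at r = 0.988 to 0.991 between libraries of the same group, at 0.981 to 0.982 between siNT and siTAZ libraries, and at 0.931 to 0.933 between siNT and siYAP libraries; genes are not independent replicates, so these values only rank the distances. The first principal component held 70.8% of the variance and the second 10.6%. Counts that fell in no annotated gene made up 4.93% ± 0.20 (SD, n = 3) of each siNT library, 6.68% ± 0.75 of each siYAP library and 5.57% ± 0.05 of each siTAZ library. The share of gene counts in mitochondrially encoded genes was 1.37% ± 0.11 after siNT, 0.876% ± 0.175 after siYAP and 1.53% ± 0.11 after siTAZ.

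The transcript targeted by each siRNA was lowest in the libraries labelled with that siRNA. YAP1 (ENSG00000137693; chromosome 11, 102110461 to 102233423, plus strand, GENCODE 29 on GRCh38) stood at 209 ± 4.11 CPM (SD, n = 3) after siNT, 26.3 ± 1.49 after siYAP and 170.0 ± 8.01 after siTAZ, with 427 to 527 counts in each siYAP library. Its level after siYAP was 87.4% below that after siNT. WWTR1 (ENSG00000018408; chromosome 3, 149517235 to 149736714, minus strand) stood at 62.0 ± 5.50 CPM after siNT, 75.8 ± 0.522 after siYAP and 9.53 ± 0.917 after siTAZ, where its level was 84.6% below that after siNT. Each siRNA also went with a smaller change of the other transcript. WWTR1 rose by 0.29 ± 0.06 on the log2 scale after siYAP (SE; edgeR, adjusted p = 6.31e-05), and YAP1 fell by 0.30 on that scale after siTAZ. An antisense gene, WWTR1-AS1, overlaps WWTR1, and the strand setting of the counting is not given in the sources used here.

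**Figure D1:**
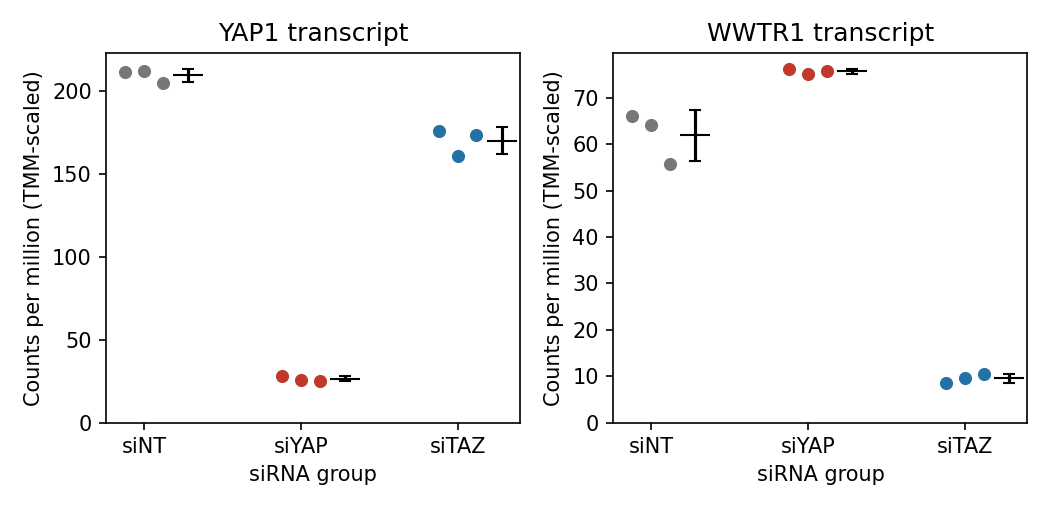
YAP1 (left) and WWTR1 (right) in each library, in CPM after TMM scaling, for the siNT, siYAP and siTAZ groups; points are single libraries and the black marks beside them give the group mean and SD (n = 3). YAP1 fell from a mean of 209 CPM to 26.3 after siYAP, and WWTR1 from 62.0 CPM to 9.53 after siTAZ.

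The comparison of siYAP with siNT asked what loss of YAP does to the stellate cell transcriptome. After siYAP, inflammatory genes (29 of 31) and p53 targets (23 of 26) rose, while YAP/TAZ targets (16 of 22), contractile genes (18 of 23) and G2/M genes (39 of 39) fell. Each of these lists was called by camera and kept the call with an estimated correlation (largest adjusted p = 0.0171). CXCL8, a neutrophil-attracting chemokine, went from 32.7 ± 4.18 CPM (SD, n = 3) to 1294 ± 53.6, a 39.6-fold rise. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 20.1-fold to 1067 CPM. CCN2 (connective tissue growth factor), a direct YAP target, fell 5.52-fold from 385 ± 12.6 CPM, and TAGLN (transgelin), an actin-binding protein of contractile cells, fell 6.95-fold from 561 ± 10.3 CPM. In all, 10448 of 15560 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05 (Benjamini-Hochberg), 5254 higher and 5194 lower, a near even balance that turned without the filter on low counts (5248 higher and 5385 lower). Of the genes called, 1681 rose and 1396 fell by more than 2-fold.

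The largest rises among genes with an average log2 CPM of at least 3 were those of the chemokine CXCL5 (129-fold), the chloride channel regulator CLCA2 (124-fold), HSD11B1 (115-fold), which regenerates active cortisol, the glycosyltransferase MGAT4C (log2 6.74), the matrix protease MMP3 (stromelysin, 70.3-fold) and complement component C3 (45.8-fold). HSD11B1, MGAT4C and MMP3 were low after siNT, at 0.384 ± 0.0861, 0.421 ± 0.169 and 0.907 ± 0.291 CPM (SD, n = 3). The largest falls were those of the hair keratin KRT81 (28.5-fold), SEMA3E (27.4-fold), a repulsive guidance ligand, the insulin-like growth factor binding protein IGFBP5 (24.2-fold), the procollagen C-proteinase-like TLL1 (23.8-fold), the sodium channel SCN9A (20.8-fold) and myostatin, MSTN (16.8-fold). IGFBP5 was the most abundant of these, at 4284 ± 142 CPM after siNT and 177 ± 6.42 after siYAP. KRT81 overlaps its paralog KRT86 and C3 overlaps GPR108 in the annotation, so their counts are uncertain.

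Of 22 genes in the YAP/TAZ target signature, 16 fell and 5 rose after siYAP (camera, adjusted p = 8.25e-16; adjusted p = 0.0027 with an estimated correlation). TGFB2, a transforming growth factor beta ligand, fell by 3.79 on the log2 scale (SE 0.05), CCN1 fell by 1.65 (0.03), the receptor tyrosine kinase AXL fell by 1.56 (0.03), F3 (tissue factor) fell by 1.84 (0.04) and ANKRD1 fell by 2.44 (0.06). NT5E, the ecto-nucleotidase CD73, went the other way, with 1.09 ± 0.03, as did the kinase LATS2 with 0.43 ± 0.04. Among 25 Hippo components and TEAD partners, 15 fell and 7 rose (camera, adjusted p = 0.00472), a call not kept with an estimated correlation (adjusted p = 0.133). TEAD1, TEAD2 and TEAD4 fell by 0.54, by 1.16 and by 0.29 on the log2 scale, and TEAD3 rose by 0.43.

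Contractile and myofibroblast genes fell as a group after siYAP, with 18 of 23 lower and 2 higher (camera, adjusted p = 4e-18; adjusted p = 0.0171 with an estimated correlation). The myosin light chain MYL9 fell 3.50-fold, the tropomyosin TPM1 3.15-fold and the non-muscle myosin MYH10 3.03-fold. ACTA2, alpha smooth muscle actin and the usual marker of stellate cell activation, rose 1.57-fold (log2 0.65 ± 0.08), from 22.5 ± 1.43 to 35.3 ± 2.64 CPM (SD, n = 3), and smoothelin, SMTN, rose 1.68-fold. ACTA2 overlaps FAS and ACTA2-AS1 in the annotation, so that its count is uncertain; FAS, chosen after its values were seen, rose from 8.47 to 60.3 CPM. Matrix glycoproteins and proteoglycans fell, with 14 of 21 tested members lower and 4 higher (camera, adjusted p = 4.88e-07; adjusted p = 0.0477 with an estimated correlation). SPARC fell 3.64-fold, the thrombospondins THBS2 and THBS1 3.54-fold and 2.85-fold, and fibronectin, FN1, 3.73-fold, while tenascin C, TNC, rose 1.75-fold. Among fibrillar collagens and collagen maturation genes, 11 of 25 rose and 12 fell, and the list did not pass (camera, adjusted p = 0.354). COL1A1 fell 2.04-fold from 4168 ± 38.3 CPM and COL3A1 1.56-fold, while COL1A2, the partner chain of type I collagen, rose 2.10-fold from 213 ± 13.7 CPM. The crosslinking enzyme LOX rose 1.37-fold, MMP2 (gelatinase A) 1.45-fold and the protease inhibitor TIMP1 2.56-fold, and the platelet-derived growth factor receptor PDGFRB fell 2.80-fold. Matrix proteases and their inhibitors as a list were called higher, with 13 of 26 up and 9 down (camera, adjusted p = 0.00386), but not with an estimated correlation (adjusted p = 0.138). The collagenase MMP1 rose 8.80-fold and the gelatinase MMP9 9.26-fold, and ADAMTS1 fell 3.46-fold. Focal adhesion and actin regulators were called lower, with 18 of 30 down and 10 up (camera, adjusted p = 0.0464; adjusted p = 0.285 with an estimated correlation), with the alpha-actinin ACTN4 4.37-fold lower. The integrin ITGA5 of that list rose 3.00-fold.

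All 39 tested G2/M genes fell after siYAP, with a median log2 fold change of -1.18 (camera, adjusted p = 3.47e-37; adjusted p = 0.00726 with an estimated correlation). Cyclin B1 (CCNB1) fell 3.47-fold and survivin (BIRC5) 3.92-fold, while the proliferation marker MKI67 fell 1.54-fold. Of 34 G1/S genes, 27 fell and 5 rose (camera, adjusted p = 0.000191; adjusted p = 0.217 with an estimated correlation). RRM1, the large subunit of ribonucleotide reductase, fell 3.76-fold, and E2F1 rose 1.57-fold. Among 26 p53 targets and cell cycle inhibitors, 23 rose and 3 fell (camera, adjusted p = 7.19e-31; adjusted p = 0.0043 with an estimated correlation). MDM2 rose 7.14-fold, BTG2 20.1-fold and RRM2B 4.12-fold, while CDKN1B, which encodes p27, fell 1.55-fold.

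Inflammatory cytokines and NF-kB targets rose in 29 of 31 tested cases after siYAP, with a median log2 fold change of 3.01 (camera, adjusted p = 8.51e-51; adjusted p = 0.0027 with an estimated correlation). IL1B rose 11.7-fold, CCL2 7.89-fold and IL6 8.06-fold, and CXCL12 fell 2.70-fold. CCL20 and PTGS2 (cyclooxygenase-2) had no counts after siNT and were at least 39.0-fold and 39.5-fold higher after siYAP, with 3 counts per library as the floor (both were chosen after their values were seen). The list's median stayed at 3.01 with these genes at that bound. Interferon-stimulated genes rose in 30 of 36 cases and fell in 3 (camera, adjusted p = 1.78e-05), a call lost with an estimated correlation (adjusted p = 0.32). TRIM22 rose 7.00-fold and IFI6 3.79-fold, and IFIT1 fell 1.47-fold. Of 5 tested markers of macrophages and leukocytes, 2 rose and 1 fell, and the list did not pass (camera, adjusted p = 0.186). CD68, also a lysosomal membrane protein, went from 22.3 ± 0.977 to 115 ± 2.11 CPM (SD, n = 3). PTPRC, which encodes the pan-leukocyte antigen CD45 and was chosen after its values were seen, stood at 2.60 ± 0.423 CPM after siNT and 0.147 ± 0.0365 after siYAP.

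Hypoxia-responsive genes rose in 15 of 19 cases after siYAP (camera, adjusted p = 3.69e-06; adjusted p = 0.138 with an estimated correlation), among them ANGPTL4, a lipase inhibitor, 40.5-fold. Lysosome and autophagy genes rose in 22 of 29 (camera, adjusted p = 4.88e-12; adjusted p = 0.121 with an estimated correlation), with cathepsin S, CTSS, 24.9-fold higher. Cholesterol synthesis and uptake genes fell in 19 of 25 (camera, adjusted p = 6.62e-06; adjusted p = 0.167 with an estimated correlation), with ACAT2 3.75-fold lower. Nuclear-encoded genes of oxidative phosphorylation fell in 24 of 30 and rose in 0 (camera, adjusted p = 0.00623; adjusted p = 0.224 with an estimated correlation). Of 13 mitochondrially encoded transcripts, 9 fell and 0 rose, and the list did not pass (camera, adjusted p = 0.251); their share of the counts was 0.876% after siYAP and 1.37% after siNT.

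Apart from the mitochondrially encoded transcripts, the lists that did not pass after siYAP had called members on both sides. Of the quiescent stellate cell markers 5 of 16 rose and 7 fell (camera, adjusted p = 0.274), of the TGF-beta pathway genes 14 of 26 rose and 10 fell (0.887), and of the growth factor and receptor genes 13 of 29 rose and 11 fell (0.0854). Of the basement membrane genes 7 of 17 rose and 7 fell (0.613), of the Notch genes 5 of 15 rose and 7 fell (0.887), and of the Wnt and Hedgehog genes 6 of 25 rose and 16 fell (0.0854). The metabolic lists were fatty acid and lipid storage genes with 7 of 29 higher and 12 lower (0.251), glycolysis with 14 of 24 higher and 8 lower (0.354), amino acid synthesis and ATF4 targets with 10 of 30 higher and 16 lower (0.274), and oxidative stress, iron and ferroptosis genes with 8 of 23 higher and 10 lower (0.977). Endoplasmic reticulum chaperones rose in 12 of 24 cases and fell in 6 (0.251), and cytosolic ribosomal proteins fell in 21 of 36 and rose in 3 (0.0764). Of the markers of other cell types, 4 of 8 cholangiocyte and epithelial genes rose and 3 fell (0.084), 3 of 7 endothelial genes rose and 4 fell (0.61), 1 of 8 portal fibroblast and mesothelial genes rose and 4 fell (0.301), and 1 of 8 neural and muscle genes rose and 4 fell (0.37). Hepatocyte markers had fewer than 5 tested members and were not tested as a list. The test leaned up against a negative median for fibrillar collagens (-0.00), quiescent markers (-0.07) and endothelial markers (-0.33), and down against a positive median for TGF-beta (0.21) and cholangiocyte (0.18) genes; for oxidative stress genes the mean was 0.03 with a test that leaned down.

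Of the 34 lists tested, 15 were called after siYAP, 6 higher and 9 lower, and 6 kept the call with an estimated correlation.  Counts adjusted over the list alone were the same for the called lists, except 5 higher for matrix glycoproteins, 20 lower for cholesterol and 23 higher for lysosome genes. The call for focal adhesion genes was lost on leaving out siNT replicate 1 (adjusted p = 0.0585) or siYAP replicate 1, 2 or 3 (adjusted p = 0.0581, 0.0930 and 0.0635). Of the 4205 fallen genes whose 3' UTR was searched, 15.4% held the 7-base word TGGATAA there, against 9.39% of the 3653 that rose; the word was picked from these data. YAP1 itself, SEMA3E and ACTN4, which fell, and LOX, which rose, held it at 1 site, and MGAT4C, which rose, held it at 3.

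**Figure D2:**
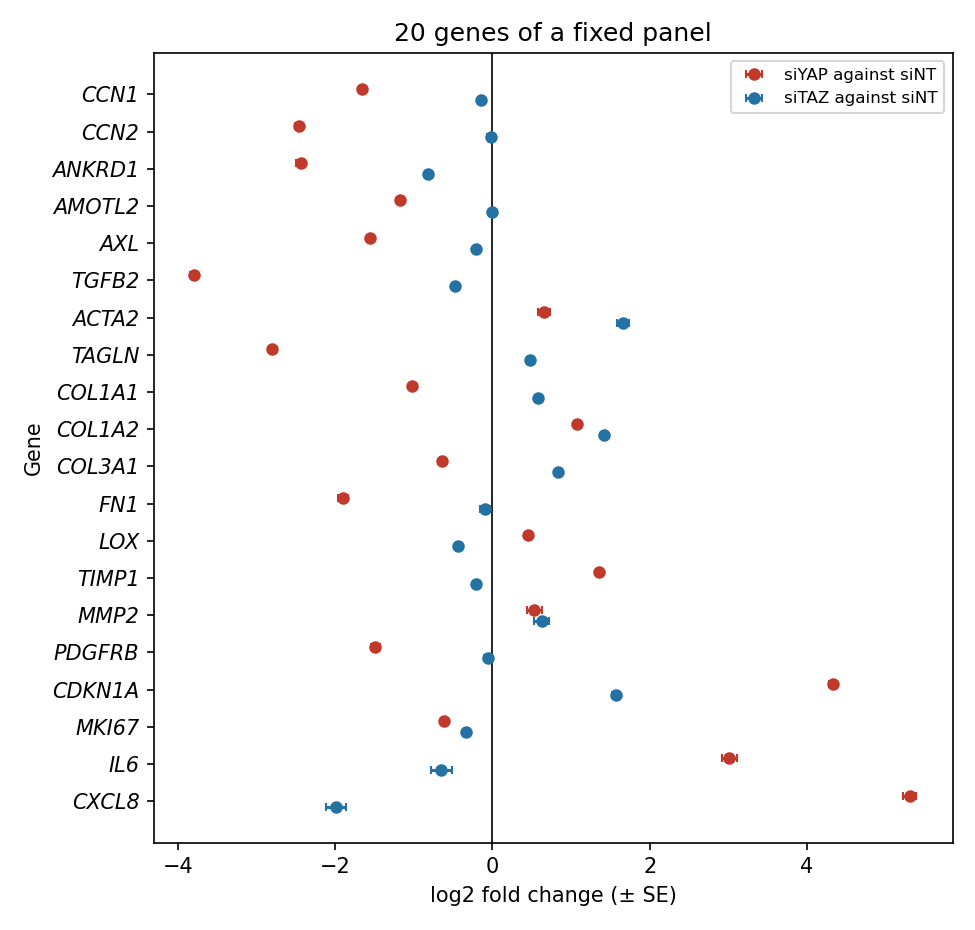
Log2 fold change of 20 genes of a fixed panel, after siYAP (red) and after siTAZ (blue), each against siNT; points are edgeR estimates and bars their SE (n = 3 libraries per group). TGFB2, TAGLN, CCN2 and ANKRD1 lie far to the left after siYAP, at -3.79, -2.80, -2.46 and -2.44, and CXCL8 and CDKN1A far to the right, at 5.31 and 4.33; after siTAZ the values span -1.99 for CXCL8 to 1.66 for ACTA2.

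The comparison of siTAZ with siNT asked the same of TAZ. Changes were smaller, with fibrillar collagens (19 of 25) and p53 targets (18 of 26) higher and matrix proteases (12 of 26) and YAP/TAZ targets (11 of 22) lower. Each of these lists was called by camera and kept the call with an estimated correlation (largest adjusted p = 0.0471). ACTA2 rose 3.16-fold, to 71.1 ± 2.17 CPM (SD, n = 3). COL1A2 rose 2.67-fold to 569 ± 19.1 CPM, COL3A1 1.78-fold to 2042 ± 54.8 and COL1A1 by 0.59 on the log2 scale to 6255 ± 38.3. CXCL8 fell 3.98-fold, to 8.17 ± 1.28 CPM. In all, 5391 of 15560 genes passed edgeR's test at an adjusted p under 0.05, 2559 higher and 2832 lower, and 187 rose and 275 fell by more than 2-fold. Upper-quartile scaling turned the balance of higher and lower genes, to 2865 and 2616, as did leaving out genes whose 3' UTR holds a word related to either siRNA group, to 1483 and 1408, an alternative chosen after seeing the data.

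Among genes with an average log2 CPM of at least 3, the largest rises after siTAZ were those of CLCA2 (6.77-fold), the neuronal pentraxin NPTX1 (5.87-fold), the inositol phosphatase INPP5D (5.33-fold), the long non-coding RNA PURPL (4.01-fold), SPATA18 (3.97-fold), a p53 target in mitochondrial quality control, and the tetraspanin TSPAN2 (3.68-fold). Besides WWTR1 itself, at 6.51-fold lower, the largest falls were those of SEMA3E (6.29-fold), the cytokine CSF2 (4.85-fold), HSD11B1 (4.84-fold), the serpin SERPINB7 (4.44-fold) and the netrin NTN4 (4.06-fold). CSF2 and HSD11B1 were low, at 2.01 ± 0.563 and 0.384 ± 0.0861 CPM after siNT (SD, n = 3), and HSD11B1 had an SE of 0.66 on the log2 scale (edgeR, adjusted p = 0.00463). The mean of HSD11B1 after siTAZ lay below the level of 3 counts, so the size and rank of its fall are poorly determined.

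The YAP/TAZ target signature fell after siTAZ, with 11 of 22 members lower, 1 higher and a median log2 fold change of -0.11 (camera, adjusted p = 0.000402; adjusted p = 0.0471 with an estimated correlation). ANKRD1 fell 1.76-fold, F3 1.55-fold and TGFB2 1.39-fold, whereas CCN2 and AMOTL2 had log2 fold changes of -0.02 ± 0.04 and -0.00 ± 0.04 and did not pass (edgeR, adjusted p = 0.744 and 1). CCN1 fell 1.10-fold and AXL 1.16-fold. Hippo components and TEAD partners fell in 15 of 25 cases and rose in 3 (camera, adjusted p = 4.09e-06; adjusted p = 0.047 with an estimated correlation), with FRMD6 1.61-fold and TAOK1 1.64-fold lower. TEAD2 fell 1.42-fold and TEAD3 rose 1.29-fold.

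Fibrillar collagens and collagen maturation genes rose, with 19 of 25 higher and 5 lower (camera, adjusted p = 6.47e-15; adjusted p = 0.047 with an estimated correlation). COL5A1 rose 1.63-fold, while PLOD2 and LOX, which hydroxylate and crosslink collagen, fell 1.52-fold and 1.35-fold. Matrix proteases and their inhibitors fell in 12 of 26 cases and rose in 6 (camera, adjusted p = 2.35e-06; adjusted p = 0.047 with an estimated correlation). ADAMTS1 fell 3.16-fold and MMP1 2.86-fold, whereas MMP2 rose 1.54-fold; TIMP1 fell 1.16-fold. Contractile and myofibroblast genes were called higher, with 12 of 23 up and 6 down (camera, adjusted p = 0.000848; adjusted p = 0.194 with an estimated correlation). MYL9 rose by 0.59 on the log2 scale and TAGLN 1.39-fold, while MYOCD, the coactivator myocardin, fell 2.81-fold. Basement membrane genes rose in 9 of 17 (camera, adjusted p = 0.000237; adjusted p = 0.149 with an estimated correlation), focal adhesion and actin regulators in 12 of 30 with 10 lower (camera, adjusted p = 0.00253; adjusted p = 0.16 with an estimated correlation), and matrix glycoproteins in 6 of 21 with 5 lower (camera, adjusted p = 0.03; adjusted p = 0.238 with an estimated correlation). Versican, VCAN, rose 2.75-fold and biglycan, BGN, fell 2.11-fold. FN1 and PDGFRB had log2 fold changes of -0.09 ± 0.06 and -0.06 ± 0.05 and did not pass (edgeR, adjusted p = 0.302 and 0.348); FN1 passed without the filter on low counts (0.00373), with limma-voom (0.00212), in a fit over these groups alone (0.00249) and with the replicate number as a block (0.0189).

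Of 26 p53 targets and cell cycle inhibitors, 18 rose and 3 fell after siTAZ (camera, adjusted p = 3.3e-08; adjusted p = 0.0471 with an estimated correlation). CDKN1A rose 2.97-fold and BTG2 3.04-fold, and TNFRSF10B fell 1.54-fold. G2/M genes fell in 26 of 39 cases and rose in 0 (camera, adjusted p = 2.47e-07; adjusted p = 0.149 with an estimated correlation), and G1/S genes fell in 18 of 34 and rose in 3 (camera, adjusted p = 0.000128; adjusted p = 0.194 with an estimated correlation). ANLN fell 1.51-fold and MKI67 1.26-fold. Amino acid synthesis genes and ATF4 targets rose in 15 of 30 cases and fell in 0 (camera, adjusted p = 9.89e-05; adjusted p = 0.0471 with an estimated correlation), with the amino acid transporter subunit SLC3A2 1.46-fold and SESN2 1.91-fold higher. Inflammatory cytokines and NF-kB targets fell in 14 of 31 cases and rose in 4 (camera, adjusted p = 0.0105; adjusted p = 0.238 with an estimated correlation). IL6 fell 1.57-fold and TNFAIP2 1.77-fold, whereas CCL5 rose 3.38-fold. Interferon-stimulated genes rose in 23 of 36 (camera, adjusted p = 4.09e-06; adjusted p = 0.238 with an estimated correlation), with TRIM22 2.14-fold and IFI44L 6.63-fold higher.

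Lysosome and autophagy genes rose in 13 of 29 after siTAZ and fell in 4 (camera, adjusted p = 0.000303; adjusted p = 0.259 with an estimated correlation), and endoplasmic reticulum chaperones rose in 13 of 24 and fell in 3 (camera, adjusted p = 0.0429; adjusted p = 0.368 with an estimated correlation). Cholesterol genes fell in 16 of 25 (camera, adjusted p = 0.000237; adjusted p = 0.194 with an estimated correlation) and glycolysis genes in 10 of 24 (camera, adjusted p = 0.00228; adjusted p = 0.319 with an estimated correlation), with HMGCS1 1.30-fold and LDHA 1.33-fold lower. Growth factor and receptor genes fell in 8 of 29 and rose in 7 (camera, adjusted p = 0.00251; adjusted p = 0.0508 with an estimated correlation), with the hepatocyte growth factor receptor MET 2.35-fold lower. Endothelial markers fell in 5 of 7 tested cases (camera, adjusted p = 6.75e-05; adjusted p = 0.0859 with an estimated correlation), with the receptor TIE1 2.90-fold lower, and portal fibroblast and mesothelial markers fell in 6 of 8 (camera, adjusted p = 0.0166; adjusted p = 0.136 with an estimated correlation), with BNC1 1.77-fold lower.

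Lists that did not pass after siTAZ were quiescent stellate cell markers, with 4 of 16 higher and 3 lower (camera, adjusted p = 0.887), TGF-beta genes, with 9 of 26 higher and 7 lower (0.931), fatty acid genes, with 4 of 29 higher and 9 lower (0.152), and hypoxia-responsive genes, with 5 of 19 higher and 5 lower (0.662). Oxidative stress genes rose in 6 of 23 cases and fell in 6 (0.887), Notch genes rose in 2 of 15 and fell in 5 (0.533), and Wnt and Hedgehog genes rose in 8 of 25 and fell in 4 (0.975). Ribosomal protein genes fell in 15 of 36 and rose in 0 (0.0966), nuclear-encoded oxidative phosphorylation genes fell in 11 of 30 and rose in 1 (0.18), and 0 of 13 mitochondrially encoded transcripts passed (0.662). Among cell type markers, 1 of 8 cholangiocyte genes rose and 2 fell (0.512), 2 of 5 macrophage and leukocyte genes fell (0.0719) and 3 of 8 neural and muscle genes fell (0.18). The test leaned down for hypoxia and Notch genes, whose medians were 0.02 and 0.15.

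Of the 34 lists, 21 were called after siTAZ, 10 higher and 11 lower, and 6 kept the call with an estimated correlation. Counts adjusted over the list alone differed by at most 2 genes in a direction for any called list. The call for matrix glycoproteins was lost without siNT replicate 3 or siTAZ replicate 1 (adjusted p = 0.0794 and 0.0641), as was that for endoplasmic reticulum chaperones (adjusted p = 0.0646 and 0.0653). Of the 2426 fallen genes whose 3' UTR was searched, 16.3% held the word CATGAAC there, against 6.93% of the 2178 that rose; this word too was picked from these data. NTN4, TAOK1, PLOD2, ANLN and MET, which fell, held this word, as did FAS, which gained 9.88 CPM after siTAZ. Transcripts of YAP1 held it outside the 3' UTR.

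**Figure D3:**
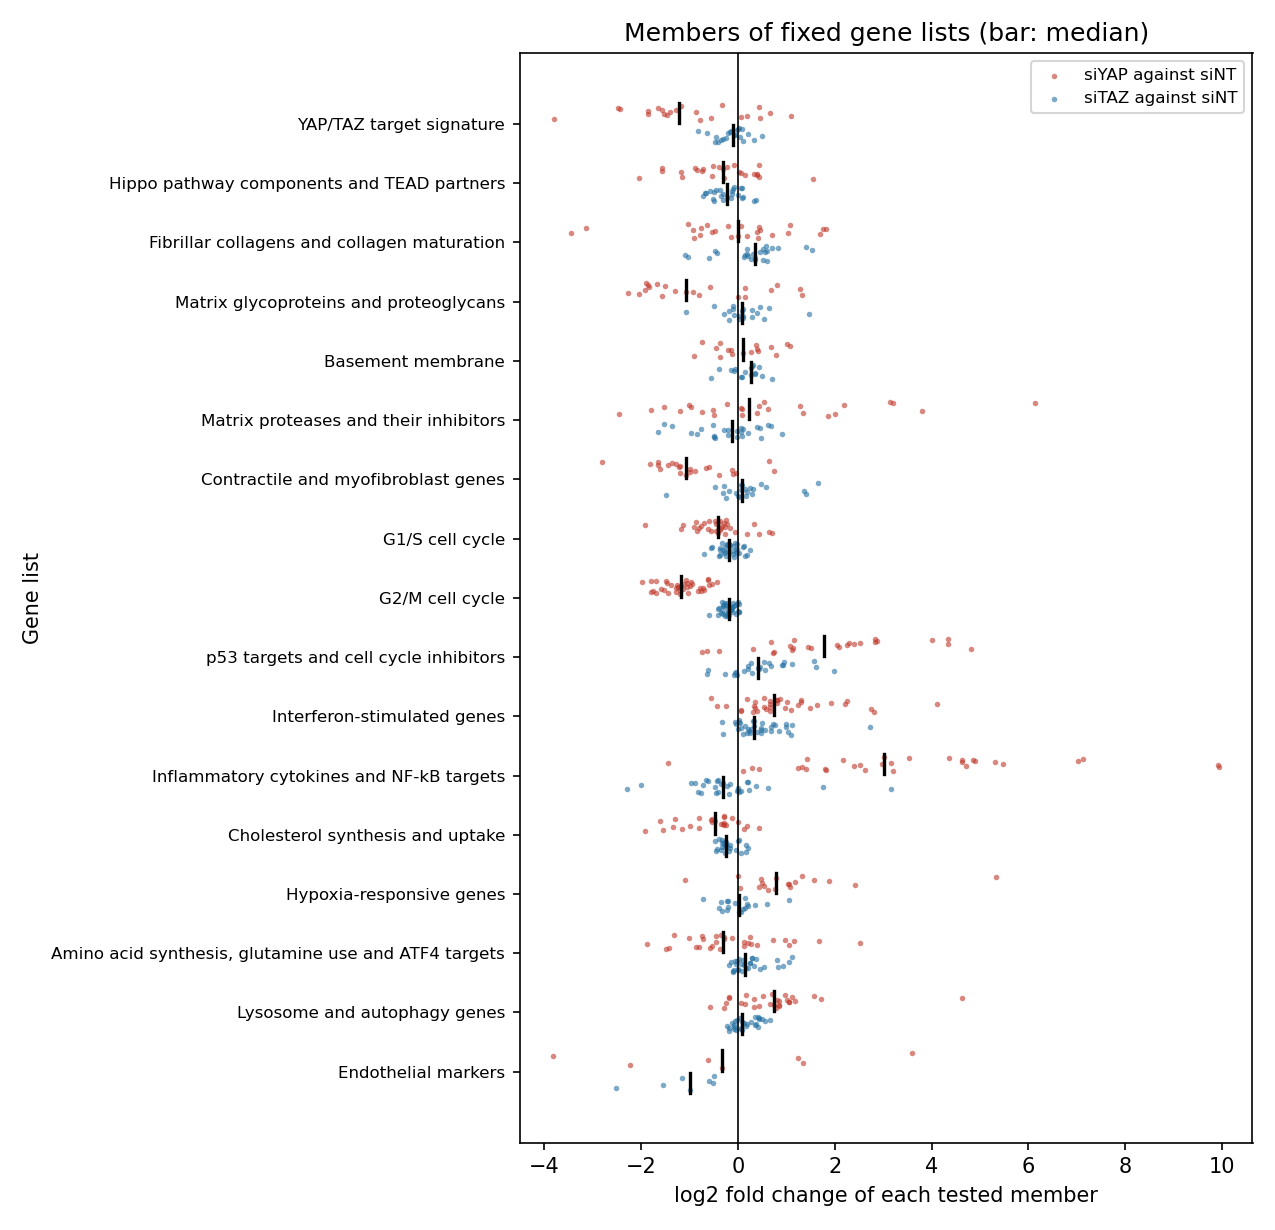
Log2 fold change of each tested member of 17 fixed gene lists, after siYAP (red) and after siTAZ (blue), each against siNT; points are genes and black bars the list medians, and the lists drawn are those with an adjusted p under 0.001 in either comparison by camera. G2/M genes lie to the left of 0 after siYAP (median -1.18) and nearer to it after siTAZ (-0.19), and inflammatory genes to the right after siYAP (3.01) and to the left after siTAZ (-0.32). The points near 10 on the x axis are fitted values of CCL20 and PTGS2, which had no counts after siNT.

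The direct comparison of siTAZ with siYAP asked where the knockdowns differed. Inflammatory genes (29 of 31), p53 targets (22 of 26) and matrix proteases (15 of 26) were lower after siTAZ than after siYAP, and YAP/TAZ targets (16 of 22), contractile genes (19 of 23) and G2/M genes (39 of 39) were higher. Each of these lists was called by camera and kept the call with an estimated correlation (largest adjusted p = 0.0339). CXCL8 was 158-fold lower after siTAZ, MMP1 25.2-fold lower and CDKN1A 6.78-fold lower. TGFB2 was 9.98-fold higher, TAGLN 9.69-fold higher and COL1A1 3.06-fold higher. ACTA2 and COL1A2, which rose against siNT with both siRNAs, were 2.01-fold and 1.27-fold higher after siTAZ than after siYAP, and MMP2 did not differ by the test (log2 0.09 ± 0.09; edgeR, adjusted p = 0.416), although it did without the filter on low counts (0.0315). In all, 10298 genes differed by edgeR's test, 5133 higher and 5165 lower after siTAZ, a near even balance that also turned without that filter (5293 higher and 5247 lower).

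The genes that were higher after siTAZ by the widest margin were TLL1 (27.5-fold), the natriuretic peptide precursor NPPB (15.8-fold), KRT81 (15.8-fold), IGFBP5 (13.4-fold), SCN9A (12.8-fold) and isocitrate dehydrogenase IDH1 (12.4-fold). Those lower by the widest margin were HSD11B1 (555-fold), CXCL5 (163-fold), MGAT4C (162-fold), CXCL8, CSF2 (127-fold) and MMP3 (101-fold). HSD11B1 was at 0.0723 ± 0.0826 CPM after siTAZ (SD, n = 3), so the size of its ratio is poorly determined. Counts of MGAT4C, MMP3 and CSF2 were also low without siYAP, so the sizes of their ratios are uncertain too.

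Lists called higher after siTAZ that kept the call with an estimated correlation were YAP/TAZ targets, with 16 of 22 higher (camera, adjusted p = 7.65e-12), contractile genes, with 19 of 23 higher (4.39e-25), matrix glycoproteins, with 14 of 21 higher (7.75e-10), and G2/M genes, with 39 of 39 higher (2.12e-27). Lists called lower that kept it were inflammatory genes, with 29 of 31 lower (4.77e-60), p53 targets, with 22 of 26 lower (4.06e-23), and matrix proteases, with 15 of 26 lower (6.02e-07). Among these 7, the proteases had the largest adjusted p with an estimated correlation (0.0339). Fibrillar collagens were higher in 14 of 25 cases and lower in 7 (camera, adjusted p = 0.0354; adjusted p = 0.347 with an estimated correlation), with COL6A2 2.56-fold lower. Focal adhesion genes were higher in 19 of 30 (camera, adjusted p = 7e-04; adjusted p = 0.134 with an estimated correlation), G1/S genes in 22 of 34 (camera, adjusted p = 0.034; adjusted p = 0.486 with an estimated correlation) and cholesterol genes in 14 of 25 (camera, adjusted p = 0.00308; adjusted p = 0.322 with an estimated correlation). Amino acid and ATF4 genes were higher in 18 of 30 (camera, adjusted p = 0.00647; adjusted p = 0.118 with an estimated correlation) and oxidative phosphorylation genes in 20 of 30 (camera, adjusted p = 0.0298; adjusted p = 0.341 with an estimated correlation). Lower after siTAZ were 17 of 19 hypoxia genes (camera, adjusted p = 3.52e-07; adjusted p = 0.118 with an estimated correlation), 23 of 29 lysosome genes (camera, adjusted p = 2.39e-08; adjusted p = 0.144 with an estimated correlation) and 17 of 24 glycolysis genes (camera, adjusted p = 0.0298; adjusted p = 0.521 with an estimated correlation). Interferon-stimulated genes were lower in 23 of 36 (camera, adjusted p = 0.0184; adjusted p = 0.579 with an estimated correlation), endothelial markers in 4 of 7 (camera, adjusted p = 0.0349; adjusted p = 0.341 with an estimated correlation) and macrophage and leukocyte markers in 2 of 5 (camera, adjusted p = 0.034; adjusted p = 0.144 with an estimated correlation), namely CD68 and CSF1R.

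Counts adjusted over the list alone differed from these by at most 1 gene in a direction. Leaving out single libraries ended the call for fibrillar collagens (without siYAP replicate 3, adjusted p = 0.0509), interferon-stimulated genes (without siYAP replicate 1, 0.0559) and the macrophage list (without siYAP replicate 1, 2 or 3 or siTAZ replicate 1, 0.0651, 0.0617, 0.0677 and 0.0872). The fibrillar collagen call was also lost with a stricter filter (0.0564). The remaining 15 lists did not pass.

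These were Hippo components, with 11 of 25 higher and 9 lower after siTAZ (camera, adjusted p = 0.337), basement membrane genes, with 7 of 17 higher and 5 lower (0.374), quiescent markers, with 6 of 16 higher and 8 lower (0.233), TGF-beta genes, with 11 of 26 higher and 11 lower (0.852), and growth factor genes, with 9 of 29 higher and 15 lower (0.509). Fatty acid genes were higher in 15 of 29 cases and lower in 12 (0.509), endoplasmic reticulum chaperones higher in 10 of 24 and lower in 11 (0.731), and oxidative stress genes higher in 8 of 23 and lower in 7 (0.935). Notch genes were higher in 6 of 15 and lower in 6 (0.911), Wnt and Hedgehog genes higher in 13 of 25 and lower in 4 (0.066), ribosomal protein genes higher in 17 of 36 and lower in 7 (0.237), and mitochondrially encoded transcripts higher in 10 of 13 (0.153). Cholangiocyte markers were higher in 3 of 8 and lower in 4 (0.106), portal fibroblast markers higher in 3 of 8 and lower in 3 (0.911), and neural and muscle markers higher in 2 of 8 and lower in 1 (0.771). The median and the test differed in sign for Hippo (-0.00), growth factor (-0.27), Notch (0.45) and oxidative stress (0.06) genes.

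Of the genes called against siNT, 4339 were called with both siRNAs. Of these, 1403 rose with both, 1633 fell with both, and for 1303 the directions were opposite (665 higher after siYAP and lower after siTAZ, 638 the reverse). Independent lists of these sizes would share 864 risen and 945 fallen genes, and 956 and 854 in the opposite directions. Groups simulated with no effect against the same controls gave a mean of 0.02 genes called in the same direction, and at most 1. In any simulation at most 3 genes were called after siYAP, so a small overlap was given beforehand. It does not show what shared controls add to the overlap of the longer lists here. Both comparisons use the same 3 control libraries, which cannot be divided into parts of at least 2, so the overlap was not measured with separate controls. Across genes the fold changes correlated at r = 0.23 (rho = 0.27), against a mean r of 0.503 that the shared controls gave with no effect, and their covariance was 0.124 against a simulated mean of 0.0329. All 1303 genes with opposite directions also differed in the direct comparison, which follows nearly by itself from opposite calls against the same controls. Of the genes called after siYAP and not after siTAZ, 5329 differed in the direct comparison, and of those called after siTAZ and not after siYAP, 838 did.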

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

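Of the tests below, that of FAS reads as a source of the ACTA2 rise after siYAP was chosen after the result was seen. For single genes called in opposite directions after siYAP and siTAZ, a called difference between the siRNAs is nearly given beforehand. A called difference was also part of the rule that flagged both genes and lists, so it lends them no further support. Several genes and lists were called in opposite directions, and the direct comparison of siTAZ with siYAP called the difference. For the genes, as log2 fold changes of siTAZ minus siYAP, these were TAGLN at 3.28, COL1A1 at 1.61, COL3A1 at 1.48, LOX at -0.89, TIMP1 at -1.56, IL6 at -3.66 and CXCL8 at -7.30, each with all 3 libraries of a group on the same side of the other group. Among the lists, the difference was called for matrix glycoproteins (camera, adjusted p = 7.75e-10), matrix proteases and their inhibitors (6.02e-07), contractile genes (4.39e-25), focal adhesion genes (7e-04) and inflammatory genes (4.77e-60). With an estimated correlation the difference was lost for focal adhesion genes (adjusted p = 0.134), and each list lost a call against siNT. The opposite directions of the lists are therefore uncertain. Lost after siTAZ were matrix glycoproteins (adjusted p = 0.238 with an estimated correlation), contractile genes (0.194), focal adhesion genes (0.16) and inflammatory genes (0.238), and after siYAP matrix proteases (0.138) and focal adhesion genes (0.285). Counts outside annotated genes, which no comparison used, were above the siNT mean of 4.93% after siYAP (6.68%) and after siTAZ (5.57%). Among the siYAP libraries, replicate 1 differed more from replicates 2 and 3 (chi-square per gene 5.03 and 3.82) than these did from each other (2.68). Correlations of log2 CPM ranked the pairs otherwise, at r = 0.9909 and 0.9905 for replicate 1 with replicates 2 and 3, and 0.9900 between these. Replicate 1 held the largest share of counts outside annotated genes (7.49%, against 6.01% and 6.53%). Whether replicate 1 is an outlier was not tested, and without it 10072 genes were called after siYAP, against 10448 with it.

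Inflammatory genes rose after siYAP in 29 of 31 cases, while after siTAZ 14 fell, 4 rose and 13 were not called (camera, adjusted p = 0.0105; adjusted p = 0.238 with an estimated correlation). Removing a trend with GC content and transcript length left their median log2 fold change after siYAP at 2.84 (bootstrap interval 2.19 to 4.39), against 3.01 before, with values for 31 of 31 members. Leukocytes mixed into the siYAP libraries would bring their own transcripts, but of PTPRC, TYROBP, FCER1G, AIF1 and CD14 the highest was CD14 at 10.2 CPM (9.22 to 11.2, mean less and plus the SD), against 9.96 CPM after siNT and 1294 CPM for CXCL8; CD68, which siNT cells also express, did rise to 115 CPM. Loss of YAP, a response to the siYAP reagent as RNA and its effects on other transcripts stay open and were not separated.

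Some genes moved apart from their lists or partners. ACTA2 rose after both siRNAs while most contractile genes fell after siYAP, and COL1A1 fell while COL1A2 rose. If a fixed share of FAS reads were counted for the overlapping ACTA2, the gains would keep 1 ratio, but that of ACTA2 to FAS was 19.9 times as high after siTAZ (48.6 and 9.88 CPM) as after siYAP (12.8 and 51.8 CPM; 15.7 to 26.9 with the means varied by their errors), and even if all ACTA2 counts after siYAP came from FAS, FAS would bring at most 10.7 CPM after siTAZ. This argues against FAS for the rise after siTAZ, but after siYAP 24.8% of the FAS gain (18.2% to 31.4%) would equal the ACTA2 gain, so FAS stays open there. For the collagen pair, genes matched in GC content and length to COL1A2 and to COL1A1 differed by 0.0651 on the log2 scale (bootstrap interval -0.09 to 0.22), against 2.10 for the pair itself. Reads of STAMBPL1 or ACTA2-AS1 and a biological difference in how these genes respond also stay open, and neither was tested.

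Each count of called genes was set against the other splits of the same 6 libraries. For siYAP with siNT the real value was 10448 genes and the highest other split gave 0; for siTAZ with siNT these were 5391 and 0, and for siTAZ with siYAP 10298 and 0. For called lists they were 15 and 13, 21 and 7, and 19 and 12. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split mixes libraries of both groups on each side, so it keeps part of the real difference and widens the spread within its groups. The values of these other splits are therefore not chance levels.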

How the results depend on the processing

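The counts of called genes, the list counts, the overlap and the targets were recomputed under the alternatives chosen for each; list counts and the overlap were not recomputed with upper-quartile scaling, no filter, a fit over the compared groups alone, limma-voom or a fold of 1.5, list counts also not with DESeq2 or an adjusted p under 0.01, and targets with neither that p nor that fold as the threshold. Of these values, 177 kept their direction and their side of the threshold, or for counts stayed within 1.5 times; 10 were weaker, 2 were stronger and 0 reversed. Leaving out single libraries gave 9995 to 10089 genes for siYAP, 4576 to 4889 for siTAZ and 9832 to 10028 for siTAZ with siYAP, and 14 to 16, 19 to 22 and 17 to 19 lists. DESeq2 gave 10145, 4990 and 10018 genes, which held 97.0%, 92.2% and 97.2% of the genes called by edgeR. Scalings moved the median log2 fold change of all genes by at most 0.0323. The balance of higher and lower genes turned in several settings. For siYAP it was 5248 and 5385 without the filter, 5242 and 5280 over the compared groups alone, 4591 and 4654 at an adjusted p under 0.01, 4978 and 5033, 4952 and 5075, and 4989 and 5045 without siNT replicates 1, 2 and 3, and 4965 and 5107 without siYAP replicate 1. For siTAZ with siYAP it was 5293 and 5247 without the filter, 5017 and 4952 with the stricter one, 4979 and 4903, and 4942 and 4909 without siYAP replicates 1 and 2, and 4979 and 4967, 5034 and 4994, and 4996 and 4949 without siTAZ replicates 1, 2 and 3. For siTAZ it turned with upper-quartile scaling (2865 and 2616) and without genes holding either 6-base word (1483 and 1408).

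With the replicate number as a replicate block, 10434, 5413 and 10268 genes were called, of which 10379, 5328 and 10220 were also called without it, and 15, 19 and 19 lists; the overlap in the same direction was 3051 genes. The labels do not say that equal numbers pair the libraries, and residuals of equally numbered libraries correlated at r = -0.00986 to 0.0540 across genes. With the block, camera no longer called focal adhesion genes after siYAP (adjusted p = 0.106), nor matrix glycoproteins (0.217), focal adhesion (0.0686) or growth factor genes (0.111) after siTAZ, while FN1 passed after siTAZ (edgeR, adjusted p = 0.0189); the cause was not tested.

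Testing against a fold of 1.5, which asks for larger changes by construction, left 3852, 342 and 3633 genes. With an estimated correlation, 6, 6 and 7 lists were called, and the cause was not tested; fry, which does not compare a list with other genes, called 33 for siYAP and 32 for siTAZ with siYAP. Leaving out 5574 genes whose 3' UTR holds either 6-base word, chosen after seeing the data, left 9986 tested genes and so fewer calls: 6245 (3384 higher and 2861 lower), 2891 and 6096 genes, an overlap of 1681 in the same direction, and for siYAP, siTAZ and siTAZ with siYAP 62.5%, 28.95% and 61.0% of the genes tested, against 67.1%, 34.6% and 66.2% with all genes. There the calls for Hippo genes after siYAP (adjusted p = 0.483) and, after siTAZ, matrix glycoproteins (0.579), focal adhesion (0.466), growth factor (0.742), endoplasmic reticulum (0.351) and portal fibroblast genes (0.195) were lost, as was that for amino acid genes in the direct comparison (0.188); whether through fewer members or their words was not tested. Of 55 list calls, 46 were kept and 7 lost. The others had fewer than 5 members left and could not be tested again. A stricter filter ended the call for focal adhesion genes after siYAP (0.0603). Of 5549 values for single genes, 23 changed side, 9 of them to a call, and of 657 for single lists, 63 lost a call. Depth limits genes near 0.157 to 0.177 CPM, the level of 3 counts.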

Other observations

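Of the tests below, those of the words' specificity, of the words in the target transcripts and of microRNA matches were added after the strongest words had been seen, and the words themselves were picked from these data. CLCA2 rose with both siRNAs, by 6.96 and 2.76 on the log2 scale after siYAP and siTAZ, as did the p53-responsive SPATA18 (4.82 and 1.99), the non-coding RNA PURPL (5.50 after siYAP) and INPP5D (4.73 and 2.42). SEMA3E fell with both, at -4.77 and -2.65. CSF2 and SERPINB7 moved in opposite directions, at 4.71 and 4.29 after siYAP and at -2.28 and -2.15 after siTAZ.

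An siRNA can also lower transcripts whose 3' UTR matches its seed, and a 7-base word stood out in each group. Other words passed the 95th percentile of permutations too. In all, 17 words passed on the lower side after siYAP, among them TGTGTTA (t = -6.21), which lacks the 6-base word GGATAA. For siTAZ, 16 passed on the lower side and 3 on the higher side, GGTGCTA, TACCTCA and CTACCTC (t = 5.28, 5.01 and 4.99). What these 3 words stand for was not tested. After siYAP, TGGATAA went with lower values (t = -9.40; strongest word on the higher side 4.38; 95th percentile of permutations 4.67), and after siTAZ, CATGAAC did (t = -13.9; 5.28; 4.59), while each word had little relation to the other siRNA's changes (t = -1.31 for the siYAP word after siTAZ and -1.28 for the siTAZ word after siYAP). Median log2 fold changes with and without the word were -0.19 and -0.02 after siYAP and -0.09 and 0.01 after siTAZ; of the genes that fell over 2-fold, 21.05% of 784 held the word after siYAP and 32.5% of 80 after siTAZ, against 8.66% and 4.35% of those that rose over 2-fold and 10.6% and 8.56% of those not called, so the words could account for part of the falls and directly for none of the rises. The words also occur in 4 of 11 YAP1 transcripts and 7 of 12 WWTR1 transcripts, a weak test, since 34.5% and 33.4% of genes of like length hold them and 9 YAP1 transcripts hold the siTAZ word too. These values are consistent with seed-matched silencing by both reagents as a hypothesis, which the siRNA sequences, not used here, would test.

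Transfected siRNA may also compete with the cell's own microRNAs, which would raise their targets. Over the seed matches of 18 microRNA families, the median t was 1.47 after siYAP, with 16 of 18 above 0, and 0.567 after siTAZ, with 13 of 18 above 0. For random sets of 18 words of the same GC content, the 95th percentile of the median t was 0.462 after siYAP and 0.381 after siTAZ. Some seed matches share 6 bases with words already seen among the strongest on the higher side. Examples are TTTGCAC with TTGCACT after siYAP and ATGCTGC with TGCTGCT after siTAZ. The random sets do not allow for this overlap. The median t values are therefore not independent of the words seen before, and how much the overlap adds to them was not tested. Both groups and siNT received siRNA at 20 nM, so competition as such would not differ between them unless the reagents were taken up or loaded unequally, which was not tested.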
